A study of Mus musculus with 6 samples.

How the data were processed

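Gene expression was measured on 6 Affymetrix arrays of 45101 probe sets, with 2 arrays for each of 3 genotypes of mouse ES cells: NcGFP ki/+, NcGFP ki/ki and wild type W4. Per the labels' protocols, RNA was extracted with Trizol followed by RNeasy columns, and the biotin-labelled material was handled by the standard Affymetrix protocol. The deposited values are intensities on a linear scale, made by the authors with GCRMA and quantile normalization per the series design text, which also names simpleaffy for quality control and limma for the analysis. Their versions are not given in the sources used here. The values were read as linear because they are right skewed with medians between 49.97 and 53.3, and log2 was taken of them here. A second deposited table held the same 6 columns beside 6 columns of another series. The largest difference between the shared columns was 0, and the 6 columns of the other series were not used.

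Of the 45101 probe sets, 64 were Affymetrix controls and were left out of tests. A probe set was kept when its log2 value exceeded 4 in at least 2 of the 6 arrays, which left 37950. Probe set symbols came from the supplied table of probe genes: 34958 probe sets had a single symbol, 932 had several and 9211 had none listed. Of the single symbols, those of 34754 probe sets stood in the RefSeq gene table of mouse assembly GRCm38.p6, which was used for symbols, chromosomes and gene order. Of the kept probe sets, 30722 had a single symbol, 803 several and 6425 none. For gene lists each gene was represented by the kept single-symbol probe set with the highest mean over the 6 arrays, giving 16706 genes.

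Differences between genotypes were tested with limma 3.58.1 in R 4.3.3, with 1 fit to all 6 arrays, genotype as the only term and 3 contrasts. The p values were adjusted by Benjamini and Hochberg within each contrast, with 0.05 as the threshold. The fit had 3 residual degrees of freedom per probe set, and limma's prior added 3.57. In any contrast, the 10 largest rises and falls past the threshold were to be named, or the 5 genes with the smallest p where none passed, and 11 genes were named whatever their p. Gene lists were tested with camera at its preset correlation of 0.01 and adjusted over the lists of a contrast, for lists with at least 4 measured members. There were 30 lists with 526 different genes, of which 479 were measured, and 29 lists were tested. List members were also adjusted over the list alone, a less strict count. The lists, the tests, the thresholds and the rule for naming genes were fixed before the data were examined.

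The alternatives fixed in advance were a further quantile normalization, no filter or a stricter one (log2 above 6), a trended and robust prior, a fit with only the 4 arrays of both genotypes compared, the replicate number as a block, leaving out each array in turn, an added limit on fold change, and for lists an estimated correlation, fry in place of camera and the mean of the kept probe sets of a gene. Added after the data had been seen were the feeder marker median of each array as a covariate, array weights from limma, leaving out arrays for the lists, and a split of the controls that leaves 1 wild type array to each comparison. Leaving out an array leaves 1 array of its genotype, which is then taken to vary like the other genotypes. The correlation between both comparisons with wild type was set beside 100 simulations of unchanged groups against the same wild type arrays. The median shift of the genes of each chromosome was set beside 10000 random gene lists matched on mean signal.

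The precision was examined on simulated data with changes of known size placed in the comparison of ki/ki with wild type. Of 100 probe sets changed by 1 on the log2 scale, limma recovered 12%. The shares recovered at changes of 2 and 3 were 60% and 86%, and 1 of 86 calls was an unchanged probe set. Camera called 100 of 100 simulated lists of 20 genes shifted by 0.5 at an unadjusted p below 0.05, and 7 of 100 unshifted lists. The preset correlation of 0.01 lay far below the estimates for some lists, such as 0.867 for feeder markers and 0.949 for actin and SRF genes. For such lists the share of unshifted lists called may be higher. The root mean square of the standard deviation within genotypes was 0.234 for ki/+, 0.391 for ki/ki and 0.122 for wild type, while the fit uses 1 spread for all.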

Results

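Gene expression was measured in mouse embryonic stem (ES) cells, the cultured pluripotent cells of the early embryo, of 3 genotypes. The genotypes were cells heterozygous for a knock-in named NcGFP (NcGFP ki/+), cells homozygous for it (NcGFP ki/ki) and the wild type line W4. The series' design text gives 2 independent experiments per genotype, so each genotype had 2 arrays, numbered replicate 1 and replicate 2, and 6 arrays were used in all. The cells were grown with the cytokine LIF on diluted plates whose label, EMFI, is read here as embryonic fibroblast feeders, so RNA of feeder cells could enter the samples. Each array held 45101 probe sets, of which 37950 were bright enough to be tested. Median intensities lay between 49.97 and 53.3 and the lowest values between 5.46 and 5.78 on the 6 arrays. The number of arrays limits the precision. An exact two-sided permutation test of 2 arrays against 2 cannot give a p below 0.333, so the tests below borrow information on the spread across all probe sets with limma.

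The labels do not spell out NcGFP. From what is known of the study, and not from the labels, it is read here as N-cadherin joined to green fluorescent protein and placed in the gene of E-cadherin, Cdh1, the main adhesion molecule between ES cells. Cdh1 was measured by 1 kept probe set, whose position relative to the replaced part of the gene is not known here. Its log2 intensity was 12.17 and 12.13 in wild type replicates 1 and 2, 11.66 and 10.62 in the arrays labelled ki/+, and 9.77 and 11.09 in those labelled ki/ki. All 4 knock-in arrays were thus below both wild type arrays, but the array labelled ki/ki replicate 2 lay above the array labelled ki/+ replicate 2, so Cdh1 did not order the knock-in arrays by their labels. The genotype means were 12.15 ± 0.03 (SD, n = 2) in wild type, 11.14 ± 0.74 (SD, n = 2) in ki/+ and 10.43 ± 0.93 (SD, n = 2) in ki/ki. In limma the difference to wild type was -1.71 (log2, SE 0.48, adjusted p = 0.368) for ki/ki and -1.01 (SE 0.48, adjusted p = 0.527) for ki/+, and that between ki/ki and ki/+ was -0.71 (SE 0.48, adjusted p = 0.654). The difference between ki/ki and wild type was -1.05 (limma adjusted p = 0.171) without the array labelled ki/ki replicate 1 and -2.37 (limma adjusted p = 0.0432) without replicate 2.

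The N-cadherin gene Cdh2 had log2 intensities of 8.27 and 8.46 in wild type, 6.50 and 7.66 in the arrays labelled ki/+, and 7.88 and 9.11 in those labelled ki/ki. Its difference to wild type was 0.13 (SE 0.49, limma adjusted p = 0.966) for ki/ki and -1.28 (SE 0.49, adjusted p = 0.442) for ki/+. A second Cdh2 probe set gave 0.08 and -1.48. Without the array labelled ki/ki replicate 2 the first of these differences turned to -0.48. Across the 6 arrays Cdh2 had the same rank order as the median of the feeder fibroblast markers described next. Whether the Cdh2 probe sets lie within the inserted N-cadherin sequence is not known here, so they may not measure RNA made from the knock-in.

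The knock-in arrays differed from each other more than the wild type arrays did. Of 16706 genes, 1306 were over 2-fold apart between the arrays labelled ki/ki, 303 between those labelled ki/+ and 0 between the wild type arrays. Pearson's r across all probe sets was 0.976, 0.991 and 0.997 for these pairs, where probe sets are not independent replicates. By r the arrays labelled ki/ki did not group with each other. Those labelled ki/+ were each other's closest, for replicate 2 by a narrow margin. Both arrays labelled ki/ki had r between 0.983 and 0.985 with the wild type arrays, above that with each other. The array labelled ki/+ replicate 2 had r of 0.9905 with ki/ki replicate 1 and 0.9908 with ki/+ replicate 1. The lowest r, 0.971, was between ki/+ replicate 1 and ki/ki replicate 2. A list of 28 measured feeder fibroblast markers, among them the collagen gene Col1a1 and the extracellular matrix proteoglycan gene Dcn, had a median deviation from the gene means (log2) of -1.51 and -0.48 in the arrays labelled ki/+, 0.04 and 1.63 in those labelled ki/ki, and 0.15 and 0.27 in wild type. Control probe sets for 18S ribosomal RNA averaged 11.57, 11.54, 11.36 and 11.12 in the 4 knock-in arrays, in the order ki/+ and then ki/ki, but 7.22 and 7.12 in wild type. The Y-linked translation factor gene Eif2s3y had log2 intensities of 9.49 in the array labelled ki/+ replicate 1 and 9.13 in that labelled ki/ki replicate 2. It stood between 4.60 and 5.33 in the other 4 arrays.

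**Figure D1:**
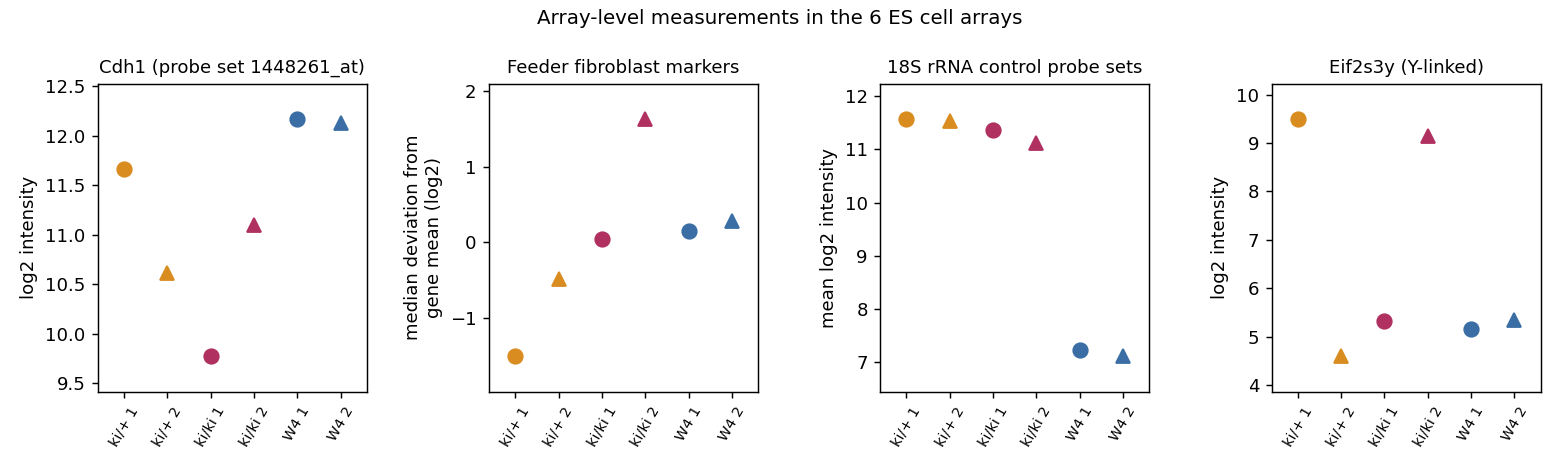
Each panel shows 1 value per array for the 6 arrays (ki/+ in orange, ki/ki in dark red, wild type W4 in blue; circles are replicate 1 and triangles replicate 2): log2 intensity of Cdh1, median deviation of the feeder fibroblast markers (log2), mean log2 intensity of the 18S control probe sets and log2 intensity of the Y-linked gene Eif2s3y. The 18S values lie between 11.12 and 11.57 in the knock-in arrays and at 7.22 and 7.12 in wild type.

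Among the transcription factor genes that hold the pluripotent state, Pou5f1 (Oct4) and Sox2 differed little between the arrays. Pou5f1 stood between 12.60 and 13.08 and Sox2 between 11.98 and 12.37, and their limma adjusted p values against wild type were 0.933 and 0.963 for ki/ki and 0.970 and 0.913 for ki/+. Nanog was at 13.08 and 11.92 in the arrays labelled ki/ki and at 12.06 and 11.95 in wild type, a difference of 0.50 (SE 0.37, limma adjusted p = 0.760) that turned to -0.09 without ki/ki replicate 1. Klf4 was at 11.58 and 10.69 in the arrays labelled ki/ki, 11.53 and 10.80 in those labelled ki/+, and 10.57 and 10.44 in wild type. It differed from wild type by 0.63 (SE 0.35, adjusted p = 0.667) in ki/ki and 0.66 (adjusted p = 0.567) in ki/+. A second Klf4 probe set gave 1.08 and 0.90 (adjusted p = 0.287 and 0.323), with all 4 knock-in arrays above both wild type arrays. Esrrb differed by -0.32 (adjusted p = 0.693) and -0.04 (adjusted p = 0.964), which was 0.10 without ki/+ replicate 2. A second Esrrb probe set gave -0.18 and 0.23, and another gave -1.07 and -0.80 (adjusted p = 0.208 and 0.282), with all 4 knock-in arrays below both wild type arrays. Zfp42 (Rex1), a marker of undifferentiated ES cells, split both knock-in genotypes: it was at 11.96 in the array labelled ki/+ replicate 1 and 11.80 in that labelled ki/ki replicate 2, and between 9.78 and 10.08 in the other 4 arrays. Ctnnb1, which encodes the cadherin-binding protein beta-catenin, differed from wild type by 0.29 (adjusted p = 0.665) in ki/ki and 0.13 (adjusted p = 0.837) in ki/+, but 2 further probe sets gave -0.01 and -0.13 in ki/ki and -0.09 and -0.48 in ki/+. The growth factor receptor gene Igf1r differed by 0.33 (adjusted p = 0.827) and -0.13 (adjusted p = 0.925), which were -0.16 without ki/ki replicate 2 and 0.01 without ki/+ replicate 1. Its 5 probe sets ran from 0.10 to 0.67 in ki/ki and from -0.13 to 0.37 in ki/+, where 3 were above 0.

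**Figure D2:**
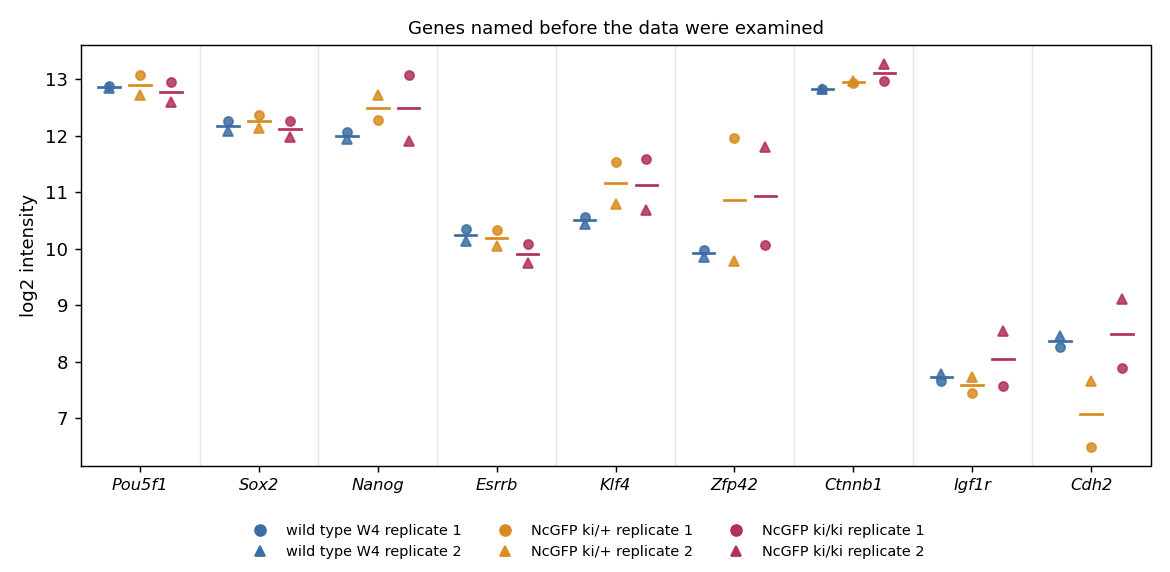
Log2 intensity (vertical axis) of 9 genes in the 6 arrays; circles are replicate 1, triangles replicate 2, bars genotype means, blue wild type W4, orange ki/+ and dark red ki/ki. Pou5f1 and Sox2 lie close together in all arrays, whereas Zfp42 differs by more than 1 unit between the arrays of each knock-in genotype.

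The comparison of ki/ki cells with wild type asked which transcripts differ when both copies of the locus carry the knock-in. The genes with the smallest p had mean log2 differences of 3.71 (SE 0.31) for Erdr1, 2.03 (SE 0.21) for the Hedgehog transcription factor gene Gli2, -2.004 (SE 0.18) for the nucleosome-binding protein gene Hmgn5, -2.56 (SE 0.23) for the long nuclear RNA Malat1 and -1.86 (SE 0.20) for Lefty2, a secreted inhibitor of Nodal signalling. Each of these lay on the same side of wild type in both arrays labelled ki/ki, but their limma adjusted p lay between 0.130 and 0.166, and 0 of 37950 probe sets passed limma's test at an adjusted p of 0.05. At an unadjusted p below 0.05 there were 3394 probe sets, where 1897.5 would be given by chance, and no other tool was run on single probe sets. The excess over chance was lost when either wild type array was left out, fits in which a lone array stands for wild type. Of the 7 kept probe sets of Malat1, 3 were below -1 and the other 4 lay above, up to 0.75. The second probe set of Erdr1 gave 0.38.

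Leaving out either array labelled ki/ki changed the count of 0. Without replicate 1, 1796 probe sets passed (1047 higher, 749 lower in ki/ki), and without replicate 2, 1046 passed (431 higher, 615 lower). In these fits the lone ki/ki array is taken to vary like the other genotypes. Both fits called 89 probe sets higher and 97 lower, and called 13 in opposite directions. Independent lists would share 11.9 and 12.1, but these fits share the wild type arrays and the ki/+ arrays that set the spread, so some overlap would arise with no effect, and no expected count was computed for that. Among genes, 31 were higher and 53 lower in both, and those named here were chosen after the values had been seen, by size of change. The genes higher in both included 3 immediate early transcription factors, Fos at 2.58, Egr2 at 1.72 and Egr1 at 1.69, together with the stress-induced factor gene Atf3 at 1.34, the cohesin loader gene Nipbl at 1.38, the amino acid transporter gene Slc7a1 at 1.30 and the actin nucleator gene Cobl at 1.30. Other probe sets differed for 3 of these: the other 4 of Nipbl gave -0.16 to 0.55, the second of Cobl gave 0.17, and those of Slc7a1 gave 1.18 and -0.17. Those lower in both included Fgf5 at -2.42 and Pou3f1 at -1.73, which mark the primed epiblast that follows the ES cell state, the kinase gene Pim2 at -1.89, the Nodal inhibitor gene Lefty1 at -1.85 and the ubiquitin-like gene Ubd at -1.81. The second probe sets of Fgf5 and Pou3f1 gave -1.35 and -1.36, and that of Egr2 gave 1.15. These log2 values are those of all 6 arrays, at which limma gave adjusted p values of 0.166 for Fos and 0.2001 for Fgf5.

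**Figure D3:**
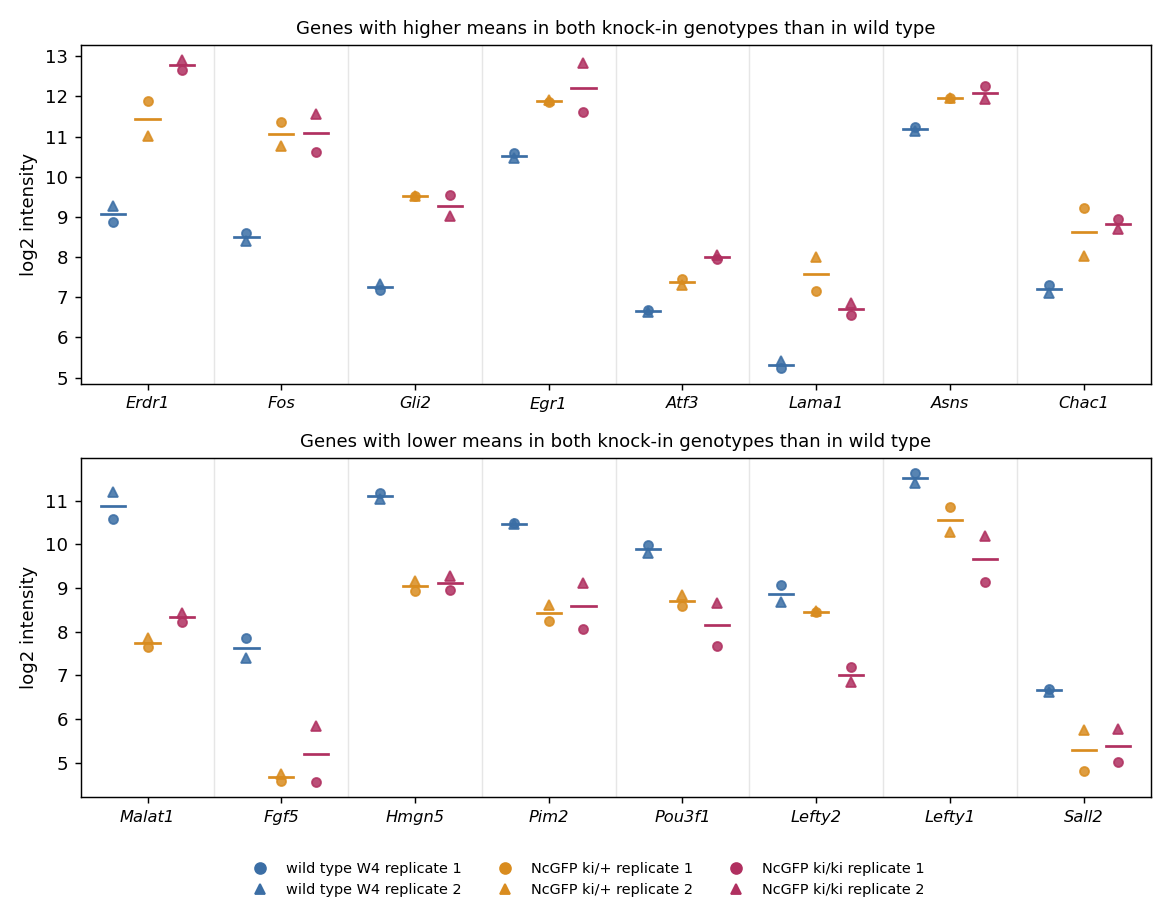
Log2 intensity (vertical axis) of 8 genes with higher means (top) and 8 with lower means (bottom) in both knock-in genotypes than in wild type; circles are replicate 1, triangles replicate 2, bars genotype means, blue wild type W4, orange ki/+ and dark red ki/ki. No gene shown passed limma's adjusted test with all 6 arrays.

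Among the gene lists set against wild type in ki/ki cells, camera with its preset correlation called 10 of the 29 lists tested. With the correlation estimated from the data, 0 of these calls held. That setting also tests on the 3 residual degrees of freedom of the fit, so a lost call need not come from correlated genes. The primed epiblast and trophectoderm lists had estimates of -0.04 and -0.03, below the preset 0.01, and lost their calls too. Primed epiblast genes fell: 17 of 18 measured members were below wild type, by a mean of -0.79 (camera adjusted p = 6.93e-09, and adjusted p = 0.184 with an estimated correlation). Over all genes tested 0 members passed, but adjusted over the list alone 6 fell: Fgf5 to a difference of -2.42, Pou3f1 to -1.73, the zinc finger gene Zic2 to -1.48, Sall2 to -1.27, Wnt8a to -0.55 and Fgf8 to -0.53. Stress response genes rose as a list, with 13 of 15 members above 0 and a mean of 0.50 (camera adjusted p = 2.49e-06, and adjusted p = 0.246 with an estimated correlation). Adjusted over the list alone 4 of them rose, and all are known targets of the integrated stress response: Chac1 by 1.61, Atf3 by 1.34, the asparagine synthetase gene Asns by 0.91 and Trib3 by 0.83, or 0.47 by its second probe set. Trophectoderm genes, which mark the outer lineage of the blastocyst, fell as a list, with 13 of 16 members below 0 and a mean of -0.47 (camera adjusted p = 6.76e-04, and adjusted p = 0.248 with an estimated correlation), and 0 members passed adjusted over the list alone. These 3 lists kept their camera calls without each of the 6 arrays in turn. They were also the lists that fry called (adjusted p = 0.0189 each). Leaving out single arrays cannot test a difference that both wild type arrays share, whether from genotype or from handling. The 18S controls set both wild type arrays apart from all knock-in arrays.

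Epithelial junction and keratin genes fell as a list in ki/ki cells, with 27 of 31 members below 0 and a mean of -0.42 (camera adjusted p = 2.67e-05, and adjusted p = 0.574 with an estimated correlation). The tight junction genes Marveld3 and Marveld2 fell adjusted over the list alone, with differences of -1.09 and -0.90, but the other probe sets of Marveld3 gave -0.14 and 0.13. Without ki/ki replicate 1 the mean was -0.22 (camera adjusted p = 0.0368). Targets of LIF and STAT3, the signal that keeps ES cells undifferentiated, rose as a list, with 14 of 16 members above 0 and a mean of 0.44 (camera adjusted p = 6.76e-04, and adjusted p = 0.574 with an estimated correlation). The single member past the threshold adjusted over the list alone was Fos, which many other signals also induce, and without ki/ki replicate 2 the list's mean was 0.23 (camera adjusted p = 0.229). Neuroectoderm genes had a mean of -0.22 (camera adjusted p = 0.0291, and adjusted p = 0.503 with an estimated correlation). That call was lost without ki/ki replicate 1 (camera adjusted p = 0.0894), without ki/ki replicate 2 (0.254) and without wild type replicate 1 (0.0546), as well as with the mean of a gene's probe sets (0.271) and with the feeder marker median as a covariate (0.0555), and 0 members passed adjusted over the list alone.

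A further 4 lists were called higher in ki/ki cells only as long as the array labelled ki/ki replicate 2, the one with the highest feeder marker levels, was included. The feeder fibroblast markers had a mean of 0.51 (camera adjusted p = 0.00259), the actin and SRF genes of the contractile cytoskeleton 0.45 (0.00952), the YAP and TAZ targets 0.44 (0.0229) and the glycolysis and hypoxia genes 0.17 (0.0138), and each had an adjusted p of 0.707 with an estimated correlation. Without ki/ki replicate 1 these means were 1.25, 1.09, 0.91 and 0.45. Without ki/ki replicate 2 they were -0.24, -0.19, -0.03 and -0.11, and none was called, with camera adjusted p values of 0.254, 0.254, 0.852 and 0.852. For glycolysis the test's direction was still upward there while mean and median were below 0. With the feeder marker median of each array as a covariate, the actin and YAP means were -0.02 and 0.08 (camera adjusted p = 0.891 and 0.350). The covariate removes the feeder list's own difference by construction, and the actin list shares 2 genes with that list. The glycolysis list had its highest median, 0.32, in the array labelled ki/+ replicate 1, where feeder markers were lowest, and its mean was 0.11 with the covariate (camera adjusted p = 0.0555). It was 0.11 with the mean of a gene's probe sets as well (camera adjusted p = 0.0735). The call for the YAP and TAZ targets was also lost without wild type replicate 1 (camera adjusted p = 0.0946). Of these lists only the glycolysis and hypoxia genes had members past the threshold adjusted over the list alone, the Myc antagonist gene Mxi1, which rose by 0.76, and the angiogenic factor gene Vegfa, which rose by 0.68. Their second probe sets gave 0.18 and -0.14.

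The comparison of ki/+ cells with wild type asked which transcripts differ when 1 copy of the locus carries the knock-in. The genes with the smallest p were Malat1 at -3.14 (SE 0.23), Hmgn5 at -2.07 (SE 0.18), Gli2 at 2.25 (SE 0.21), the angiotensin receptor gene Agtr2 at -1.64 (SE 0.18) and Nexmif at -1.64 (SE 0.19), with limma adjusted p values between 0.0921 and 0.213. The other 3 kept probe sets of Nexmif gave -0.27, 0.16 and -0.27. In limma 0 probe sets passed, 3982 had an unadjusted p below 0.05, and 1897.5 would be given by chance. Here too the excess over chance was lost when either wild type array was left out. With the 4 arrays of ki/+ and wild type alone, an alternative fixed in advance that leaves the spread of the ki/ki arrays out, 1282 probe sets passed (372 higher, 910 lower in ki/+). Leaving out either array labelled ki/ki is the same fit, since a lone array adds nothing to the spread. Leaving out 1 array of ki/+ or of wild type gave 0. At the level of genes, 189 passed as higher and 387 as lower in that fit. Genes of the X chromosome lay below wild type together in both arrays labelled ki/+, by medians of -0.25 and -0.24. Those of chromosome 8 did so by -0.14 and -0.15. How many of the lower calls lie on these chromosomes was not counted.

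The 10 largest rises in the fit with 4 arrays were those of the pyrimidine catabolism gene Dpys at 3.33, Fos at 2.55, Erdr1 at 2.38, the laminin gene Lama1 at 2.26, Gli2 at 2.25, Cyct, a cytochrome c of the testis, at 2.10, Brwd1 at 1.76, Rbm44 at 1.68, the germline piRNA factor gene Mael at 1.63 and Arrdc4 at 1.63. The 10 largest falls were those of Malat1 at -3.14, Fgf5 at -2.96, the iron exporter gene Slc40a1 at -2.54, Col1a1 at -2.45, the hyaluronan synthase gene Has2 at -2.30, Lpar4 at -2.22, Hmgn5 at -2.07, Pim2 at -2.04, Slc25a24 at -1.86 and the enkephalin precursor gene Penk at -1.84. Their limma adjusted p values in that fit lay between 0.0184 and 0.0431. Some of these genes were dim in the lower group, such as Dpys at 5.06 and 5.05 in wild type and Fgf5 at 4.58 and 4.75 in ki/+. Such values lie not far above the filter limit of 4, so the size of these differences is uncertain. Dpys had 3 kept probe sets, and the others gave 0.03 and 0.07. The second probe set of Fgf5 gave -1.12, that of Col1a1 -1.31, that of Has2 -1.80 and that of Arrdc4 1.20, and those of Lpar4 gave -1.43 and -1.48. The second probe set of Erdr1 gave 0.08, that of Rbm44 gave 0.65, the other 4 of Brwd1 gave -0.22 to 0.55, and the lowest and highest of the 7 of Malat1 gave -3.14 and -0.47. The feeder fibroblast list gave 6 of its 28 members as lower in this fit, Col1a1 among them, and 0 as higher. The feeder markers were lower in both arrays labelled ki/+ than in wild type. Col1a1, Has2 and Slc25a24 had the same rank order across all arrays as the feeder marker median, and the other falls named here did not. Whether feeder cells gave these falls was not tested.

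Camera called 12 of 29 lists in ki/+ against wild type, and 0 held with an estimated correlation. Feeder fibroblast markers fell as a list, with 28 of 28 members below 0 and a mean of -1.25 (camera adjusted p = 2.57e-13, and adjusted p = 0.489 with an estimated correlation). So did mesenchymal transition genes, with 22 of 22 members below 0 and a mean of -0.82 (adjusted p = 1.18e-08, and 0.489 as the adjusted p with an estimated correlation); 4 of these genes are also on the feeder list, and adjusted over the list alone 4 fell, among them the transcription factor genes Twist1 by 1.39 and Snai1 by 1.17. The actin and SRF genes had a mean of -0.76 (camera adjusted p = 1.79e-06, and adjusted p = 0.527 with an estimated correlation). The YAP and TAZ targets had a mean of -0.60 (camera adjusted p = 7.40e-05) and the imprinted genes one of -0.47 (2.16e-05), with an adjusted p of 0.489 for both with an estimated correlation. The imprinted genes Mirg, Igf2 and Peg10 fell when adjusted over the list alone, with differences of -1.26, -1.19 and -0.85, while second probe sets of Mirg and Igf2 gave -0.45 and -0.37. Without ki/+ replicate 1 the means of the feeder, mesenchymal, actin, YAP and imprinted lists were -0.79, -0.50, -0.44, -0.31 and -0.28, and all remained called. With the feeder marker median as a covariate, no test of the feeder list itself, the mesenchymal, actin and YAP calls were lost. Their means were then -0.04, 0.15 and 0.11 (camera adjusted p = 0.541, 0.541 and 0.368). The actin list shares 2 genes with the feeder list. Both arrays labelled ki/+ had lower feeder medians than wild type, so the covariate cannot tell feeder cells from a genotype difference. The imprinted genes remained called with the covariate, at -0.26 (camera adjusted p = 0.0419), and with the mean of a gene's probe sets at -0.29 (camera adjusted p = 0.00125).

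Primed epiblast genes were lower in ki/+ cells as well, in 16 of 18 members and by a mean of -0.61 (camera adjusted p = 6.27e-06, and adjusted p = 0.376 with an estimated correlation). This was the list that fry called here (adjusted p = 0.0380). Its camera call did not depend on any single array, although leaving out arrays cannot test a difference that both wild type arrays share. Of its members 7 fell adjusted over the list alone, the largest being Fgf5 at -2.96, Sall2 at -1.37, Pou3f1 at -1.19 and the transcription factor gene Sox3 at -1.13 (second probe set -0.27), while Zic5 rose by 0.64. The targets of p53, the regulator of cell cycle arrest and cell death, fell as a list, with 15 of 18 members below 0 and a mean of -0.44 (camera adjusted p = 3.65e-05, and adjusted p = 0.484 with an estimated correlation). With the feeder covariate their mean was -0.25 (camera adjusted p = 0.0271). Interferon response genes had a mean of -0.27 (camera adjusted p = 0.00980), and the antiviral gene Oasl2, at -0.998, was the single member past the threshold adjusted over the list alone. Trophectoderm genes had a mean of -0.30 (camera adjusted p = 0.0127), with the imprinted placental gene Peg10 lower adjusted over the list alone. The IGF and PI3K pathway genes had a mean of -0.33 (camera adjusted p = 0.00980), and adjusted over the list alone the growth factor gene Igf2 (-1.19) and the binding protein gene Igfbp4 (-1.20) fell. The adjusted p with an estimated correlation was 0.489 for each of these 3 lists. Without ki/+ replicate 1 the IGF list was not called (camera adjusted p = 0.0507). With the feeder covariate neither the IGF list (mean -0.03, camera adjusted p = 0.907) nor the trophectoderm list (mean -0.24, camera adjusted p = 0.108) was called.

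The lists called higher in ki/+ cells were the LIF and STAT3 targets and the glycolysis and hypoxia genes. The former had a mean of 0.45 with 12 of 16 members above 0 (camera adjusted p = 0.00520, and adjusted p = 0.489 with an estimated correlation), and adjusted over the list alone Fos rose by 2.55 and the NF-kappa-B cofactor gene Bcl3 by 0.71. The latter had a mean of 0.34 with 15 of 22 above 0 (camera adjusted p = 0.00670, and adjusted p = 0.612 with an estimated correlation), with the hexokinase gene Hk2 higher by 0.90 and Mxi1 by 0.81 adjusted over the list alone (second Mxi1 probe set 0.13). Without ki/+ replicate 1 their means were 0.27 and 0.07 and neither was called (camera adjusted p = 0.0652 and 0.342). Without ki/+ replicate 2 the glycolysis list's mean was 0.61, and with the mean of a gene's probe sets it was 0.25 and not called (camera adjusted p = 0.0743). Stress response genes were not called in this comparison (camera adjusted p = 0.131), but adjusted over the list alone Chac1, Trib3, Asns and Atf3 rose, by 1.42, 1.07, 0.76 and 0.72.

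**Figure D4:**
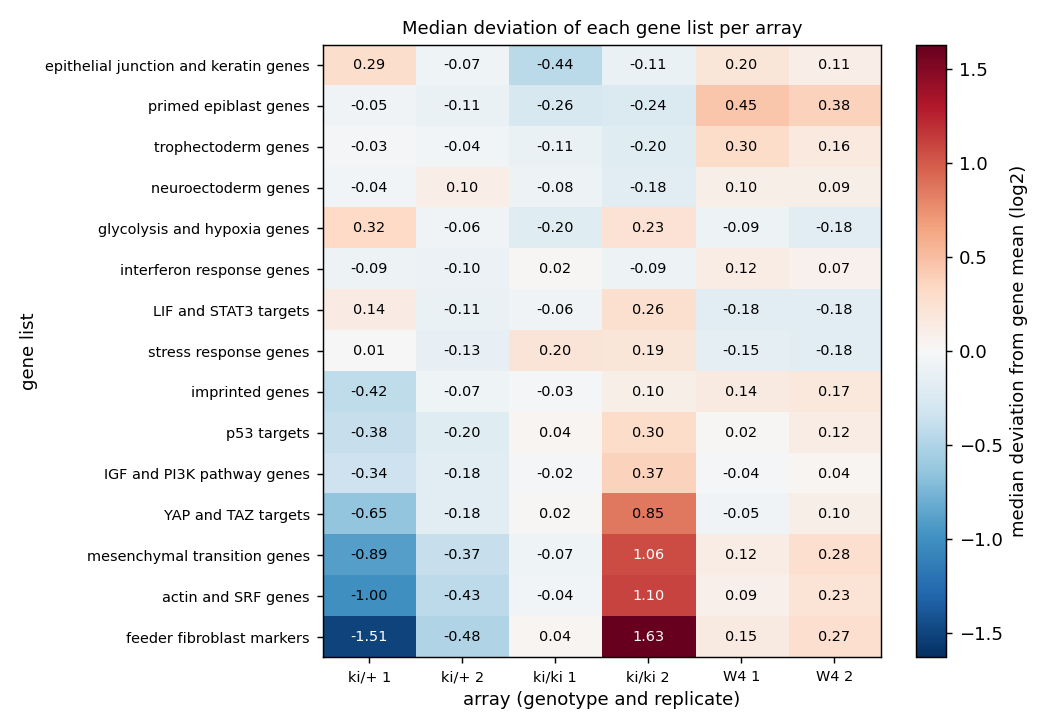
Median deviation from the gene means (log2, colour scale and printed values) of the 15 gene lists called in at least 1 comparison (vertical axis) in each of the 6 arrays (horizontal axis). The feeder fibroblast markers run from -1.51 in the array labelled ki/+ replicate 1 to 1.63 in that labelled ki/ki replicate 2, and primed epiblast genes are below 0 in the 4 knock-in arrays and above 0 in both wild type arrays.

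The comparison of ki/ki with ki/+ cells asked what the second copy of the knock-in adds; since Cdh1 did not order these arrays by their labels, each direction given here rests on the labels alone. The genes with the smallest p were the Polycomb gene Bmi1 at 1.80 (SE 0.21), the cytokine gene Tslp at 1.42 (SE 0.17), C330007P06Rik at 1.18 (SE 0.15), Marveld1 at 1.42 (SE 0.19) and Gm13261 at -1.52 (SE 0.21), each with a limma adjusted p of 0.391. In limma 0 probe sets passed, and 3899 had an unadjusted p below 0.05 against 1897.5 by chance. The latter count was 2118 in the fit with only the 4 arrays of ki/ki and ki/+, and the excess was lost without ki/+ replicate 1. Without ki/ki replicate 1, 4996 probe sets passed (3191 higher, 1805 lower in ki/ki), and without ki/ki replicate 2, 62 passed (48 higher, 14 lower). These fits had 4 higher and 3 lower probe sets in common, where independent lists would share 4.04 and 0.666, so those higher were no more than independent lists give. A further 6 were called in opposite directions, and the fits share the ki/+ and wild type arrays. The genes called in both, which were named after their values had been seen, were Marveld1 and Ripor1 as higher, and the Golgi trafficking gene Rab6b and the Rap activator gene Rasgrp2 as lower, with log2 differences of 1.42, 1.40, -1.77 and -1.35 over all arrays. A second probe set of Ripor1 gave -0.32, the lowest of the 4 of Marveld1 gave 0.10, the highest of Rab6b gave -0.47 and the highest of Rasgrp2 gave 0.19.

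The lists separating ki/ki from ki/+ cells were led by the feeder fibroblast markers, which were higher in ki/ki in 28 of 28 members with a mean of 1.76 (camera adjusted p = 3.89e-21). All 28 rose adjusted over the list alone, among them Col1a1 by 2.45, the collagen gene Col5a2 by 2.36 and the matrix gene Tnc by 2.24. The mesenchymal transition genes had a mean of 1.11 (camera adjusted p = 1.56e-12, 14 members higher adjusted over the list alone) and the actin and SRF genes 1.20 (1.88e-12, 6 members). The YAP and TAZ targets had a mean of 1.04 (2.93e-09, 5 members), the p53 targets 0.53 (6.16e-07, 0 members) and the IGF and PI3K pathway genes 0.47 (8.84e-05, 4 members). With an estimated correlation the adjusted p was 0.516 for each of the 9 lists called here. The feeder, mesenchymal, actin, YAP and IGF means were 1.01, 0.59, 0.57, 0.57 and 0.26 without ki/ki replicate 2, and the actin mean was 1.84 without ki/ki replicate 1, with all calls kept. With the feeder marker median as a covariate, no test of the feeder list itself, the other 4 of these calls were lost. Their means were then -0.06, -0.16, -0.03 and 0.01 (camera adjusted p = 0.893, 0.416, 0.951 and 0.893). Feeder level went with the genotype labels in this comparison, so the covariate cannot tell feeder cells from a genotype difference. The p53 targets remained called with the covariate, at 0.24 (camera adjusted p = 0.0483).

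The other 3 called lists also had an adjusted p of 0.516 with an estimated correlation, and they depended on single arrays. Epithelial junction and keratin genes had a mean of -0.35 in ki/ki against ki/+ (camera adjusted p = 3.76e-04), which was not called without ki/+ replicate 1 (-0.20, camera adjusted p = 0.0599) or without ki/ki replicate 1 (-0.16, 0.287) and was -0.55 without ki/ki replicate 2. Imprinted genes had a mean of 0.31 (camera adjusted p = 0.00783). That call was lost without ki/+ replicate 1 (camera adjusted p = 0.306) and without ki/ki replicate 1 (0.0614), and the mean was 0.50 without ki/+ replicate 2. It was also lost with the mean of a gene's probe sets (0.08, camera adjusted p = 0.110) and with the feeder covariate (-0.000917, camera adjusted p = 0.951). Adjusted over the list alone, the imprinted growth regulator genes Igf2, Dlk1 and Grb10 rose by 1.25, 1.24 and 0.87, Ndn rose by 1.28 and Phlda2 fell by 1.45. The second probe sets of Igf2 and Dlk1 gave 0.11 and 0.01, those of Grb10 gave 0.28 and 0.27, and the 8 of Ndn ran from -0.12 to 1.28. Stress response genes had a mean of 0.24 (camera adjusted p = 0.00240), lost without ki/+ replicate 2 (0.107) and without ki/ki replicate 1 (0.0660). The chaperone gene Hspa1b rose by 0.75 and Atf3 by 0.62 adjusted over the list alone. The feeder medians of the arrays labelled ki/ki lay above those of both arrays labelled ki/+.

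The 2 comparisons with wild type shared the same control arrays, so their fold changes correlate with no effect at all. Across 16706 genes, which are not independent replicates, Pearson's r of the 2 sets of log2 differences was 0.338 (Spearman's rho 0.328). In 100 simulations of unchanged groups against the same controls r averaged 0.111 when each genotype kept its own spread and 0.502 when all had the pooled spread. The covariance was 0.0413, against 0.0066 and 0.0419 in the simulations. Differences had the same sign for 61.3% of genes, against 53.4% and 66.6%. At an unadjusted p below 0.05, 637 probe sets were higher and 765 lower in both comparisons, where independent lists would share 69.4 and 111. With the controls split, which leaves 1 wild type array to each comparison, r was 0.197 with wild type replicate 1 set against ki/ki and replicate 2 against ki/+, and 0.355 the other way round (covariance 0.0270 and 0.0429). Part or all of the excess in shared probe sets may come from the shared controls, and no expected count that allows for them was computed. Without ki/ki replicate 1 r was -0.02, and without ki/ki replicate 2 it was 0.55.

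Of the 29 lists tested, 14 were called in no comparison: cadherins, adherens junction partners, core and naive pluripotency genes, Wnt and beta-catenin targets, mesoderm, primitive endoderm, two-cell-like and germline genes, cholesterol synthesis genes, FGF and ERK targets, Nodal targets, BMP targets and proliferation genes. Their lowest camera adjusted p was 0.0622 in ki/ki against wild type (Nodal targets), 0.0687 in ki/+ against wild type (FGF and ERK targets) and 0.0912 in ki/ki against ki/+ (two-cell-like genes). Some members of these lists passed adjusted over the list alone. In ki/ki against wild type the Nodal inhibitor genes Lefty2 and Lefty1 fell by 1.86 and 1.85, the germline gene Rhox9 fell by 2.24, the BMP feedback inhibitor gene Smad6 rose by 1.29 and the ERK-induced gene Egr1 rose by 1.69. In ki/ki cells members of lists called only in other comparisons also passed: the imprinted gene Grb10 rose by 1.01 (other probe sets -0.16 and 0.17), the imprinted gene Nnat fell by 1.94, and the interferon-induced genes Oasl2 and Bst2 fell by 0.90 and 0.86. In ki/+ against wild type Lama1 rose by 2.26 and Egr1 by 1.37. The ERK phosphatase gene Dusp4 fell by 1.82, the BMP target gene Id3 by 1.51 and Manba, a lysosomal enzyme gene of the naive list, by 1.06. The sterol synthesis gene Fdft1 rose by 0.74, where its other probe sets gave 0.26, 0.02 and 0.02. In the fit with only the 4 arrays of ki/+ and wild type, 3 naive pluripotency genes passed limma's test as higher. They were Prdm14 at 1.37, Fgf4 at 1.07 and Jam2 at 1.00, and 1 passed as lower, Manba. In ki/ki against ki/+ Lefty2 fell by 1.44, and the basement membrane collagen genes Col4a2 and Col4a1 rose by 1.89 and 1.83, together with the growth factor receptor gene Pdgfra by 1.28 and the adaptor gene Dab2 by 1.29. The lowest probe sets of Col4a1, Pdgfra and Dab2 gave 1.31, 0.44 and 0.03. From other lists Bst2 fell by 0.87, and the primed epiblast genes Zic2 and Zic5 fell by 1.33 and 0.96. Y-linked genes had 3 measured members, too few for the list test.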

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

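All tests in this part were chosen after the 18S values had been seen, although the prediction for the histone genes was written before their values were looked at. Control probe sets for 18S ribosomal RNA, which the comparisons do not use, gave a signal in the knock-in arrays above that in the wild type arrays. The mean difference (log2) was 3.57, 5.11 and 4.004 for the probe sets at the 3' end, at the 5' end and in the middle, or 18.7-fold on average. The means of the 3 probe sets were 11.57 and 11.54 in the arrays labelled ki/+, 11.36 and 11.12 in those labelled ki/ki, and 7.22 and 7.12 in wild type. The other 61 control probe sets differed by between -0.61 and 0.39.

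Degraded RNA in the knock-in samples may raise such a signal, but it would also widen the gap between the 3' and 5' probe sets of the Actb control, which differed by 0.0841 between knock-in and wild type arrays. Stronger labelling of RNA without poly(A) tails would raise the replication-dependent histone genes. Their median difference was -0.0195 (95% bootstrap interval -0.16 to 0.06), with 9 of 20 probe sets higher in the knock-in arrays. Some of these probe sets measure the same genes, so they are not independent. Handling of the wild type samples apart from the knock-in samples could leave a difference of this size (mean 4.23) and cannot be told apart from a difference between genotypes, because no label puts a knock-in and a wild type array together. No biological explanation was tested. If the wild type samples were handled apart, every comparison with wild type would carry that difference too, whereas the comparison of ki/ki with ki/+ would not.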

How the results depend on the processing

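The feeder covariate, the array weights, the split controls and the leaving out of arrays for lists were chosen after the results had been seen, and all other alternatives were fixed before. The counts of 0 probe sets held under a further quantile normalization, both other filters, the trended and robust prior, the added limit on fold change and the feeder covariate. For ki/+ against wild type 1282 probe sets passed with the 4 arrays alone and 2172 with array weights, both of which give less room to the spread of the arrays labelled ki/ki. The second deposited table was not run because its values are identical. The replicate number as a block gave 0 probe sets in all 3 contrasts and 12, 13 and 9 called lists, with correlations of the deviations of equal numbers of -0.04, 0.14 and 0.06 between genotypes. Of 671 alternative values for single genes 584 kept their sign and their side of the threshold, 45 passed the threshold and 42 reversed. Of 341 for lists 244 kept their call, 87 lost it and 10 reversed. Values counted as kept could still change in size. Dim transcripts are limited by the background, at which the lowest intensities lay between 5.46 and 5.78.

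With the correlation estimated for each list, 0, 0 and 0 lists were called in ki/ki against wild type, ki/+ against wild type and ki/ki against ki/+, and with fry 3, 1 and 0. The setting with an estimated correlation also rests on 3 residual degrees of freedom. With the mean of the probe sets of a gene, 10, 11 and 9 were called. The feeder covariate gave 8, 7 and 6, and reversed values as follows. In ki/ki against wild type they were Cdh2 -0.42, Pou5f1 0.0723, Sox2 0.0724, Col1a1 -0.72, feeder markers -0.0711 (by construction) and actin and SRF genes -0.016. In ki/+ against wild type they were Pou5f1 -0.28, Sox2 -0.16, Klf4 -0.0766, Igf1r 0.49, actin and SRF genes 0.15 and YAP and TAZ targets 0.11. In ki/ki against ki/+ they were Cdh2 -0.19, Pou5f1 0.35, Sox2 0.23, Klf4 1.09, Zfp42 -0.19, Esrrb 0.15, Ctnnb1 -0.10, Igf1r -0.49, mesenchymal genes -0.0622, actin and SRF genes -0.16 and YAP and TAZ targets -0.0322. A further quantile normalization turned Nanog in ki/ki against ki/+ to -0.00985. The cause was not tested.

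Leaving out 1 array at a time gave between 0 and 1796 probe sets in ki/ki against wild type, 0 and 1282 in ki/+ against wild type, and 0 and 4996 in ki/ki against ki/+, the highest without ki/ki replicate 1, and in ki/+ against wild type without either array labelled ki/ki, which is the fit with 4 arrays. In ki/ki against wild type the ranges were Cdh2 -0.48 to 0.75, Pou5f1 -0.27 to 0.0884, Nanog -0.0869 to 1.08, Sox2 -0.20 to 0.0957, Igf1r -0.16 to 0.81, Col1a1 -1.05 to 1.06, feeder markers -0.24 to 1.25, actin and SRF genes -0.19 to 1.09 and YAP and TAZ targets -0.0284 to 0.91. In ki/+ against wild type they were Pou5f1 -0.14 to 0.21, Sox2 -0.0295 to 0.19, Zfp42 -0.14 to 2.04, Esrrb -0.18 to 0.0983 and Igf1r -0.27 to 0.0124. In ki/ki against ki/+ they were Pou5f1 -0.30 to 0.0528, Nanog -0.58 to 0.59, Sox2 -0.28 to 0.0144, Klf4 -0.48 to 0.42, Zfp42 -1.03 to 1.15 and Igf1r -0.0297 to 0.94, with 8 to 15 lists called. The correlation of both comparisons with wild type ranged from -0.0188 to 0.55, and with the controls split it was 0.197 and 0.355. The cause was not tested.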

Other observations

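The tests of feeder markers, Y-linked signal and normalization in this part were chosen after the values had been seen, and the predictions on chromosome gain and on swapped labels were written before theirs. The genes in this paragraph and the next were chosen after the values had been seen, and differences between single arrays were not tested. The array labelled ki/ki replicate 1 stood apart in genes of the two-cell-like state, a rare state of ES cells that resembles the two-cell embryo. The median of the 4 measured genes of that list deviated from the gene means by 1.48 in this array and by between -0.53 and -0.16 in the others. The deubiquitinase gene Usp17la was at a log2 intensity of 9.98 there and between 4.06 and 5.77 elsewhere, and the arginase gene Arg2 was at 6.72 against values between 4.01 and 4.48. The germline RNA-binding protein gene Dazl was at 9.03 against 5.50 to 7.57. The naive pluripotency genes Tbx3 and Prdm14 were at 10.39 and 9.71 against at most 8.71 and 8.64. Prdm14 was also at 8.46 and 8.64 in the arrays labelled ki/+, above 7.33 and 7.03 in wild type and 7.19 in ki/ki replicate 2. In the fit with only the arrays of ki/+ and wild type it rose by 1.37 (limma adjusted p = 0.0268). In the array labelled ki/ki replicate 1 the keratin gene Krt8 was at 6.12 and the claudin gene Cldn7 at 7.47. These lay below all other arrays, where they were at least at 7.18 and 8.68.

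The LIF-responsive transcription factor gene Gbx2 followed Zfp42 across the arrays. It was at 9.09 in the array labelled ki/+ replicate 1 and 8.90 in that labelled ki/ki replicate 2, and between 6.87 and 7.50 in the other 4. These arrays were also the ones with Y-linked signal, at which a Uty probe set had 7.44 and 7.10 against 4.13 to 4.36 elsewhere. The growth factor gene Fgf4, which drives ES cells toward differentiation, was at 10.17 and 10.01 in wild type and at 10.99, 11.34, 11.92 and 10.71 in the knock-in arrays, in the order ki/+ and then ki/ki.

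Genes of whole chromosomes were shifted together in single arrays, measured against the wild type mean over 8484 genes. Of 80 pairs of chromosome and array, 15 lay beyond all random lists. Chromosome 7 had a median shift of 0.32 in the array labelled ki/+ replicate 2 and 0.33 in that labelled ki/ki replicate 1, and chromosome 11 one of 0.29 in ki/+ replicate 2. The X chromosome had -0.25 and -0.24 in the arrays labelled ki/+ and 0.45 and -0.12 in ki/ki replicates 1 and 2, the last of which did not lie beyond all random lists. Chromosome 8 had -0.14, -0.15, -0.16 and -0.14 in the 4 knock-in arrays, which a gain in the wild type cells would give as well.

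A signal-dependent bias of the normalization was tested with the random lists, and 0 of 10000 lists matched on signal reached the chromosome 7 shift of ki/+ replicate 2. A gain of whole chromosomes in the cultures may explain the shifts of chromosomes 7 and 11: their genes were shifted along the whole chromosome, and of 3 equal parts the least shifted part moved by 0.25. Feeder cells as the source of the Y-linked signal were made less likely for ki/+ replicate 1. Its feeder markers had a median difference to wild type of -1.67 (95% bootstrap interval -1.81 to -1.47). That interval is for a median over genes in 1 array, and these genes vary together, so it does not measure the spread between cultures. Feeder cells were not excluded, because the markers were lower but not absent and the sex of the feeders is not known here. For ki/ki replicate 2 that source remains open. The Cdh1, Y-linked and chromosome 7 values could also come from swapped labels of ki/+ replicate 2 and ki/ki replicate 2, which cannot be told apart from shared descent of clones, whereas the X chromosome (-0.24 against 0.45) and chromosome 11 (0.29 against -0.0805) set ki/+ replicate 2 apart from ki/ki replicate 1, the pair that a swap would join. The test set for it gave 0.901, but independent noise alone gave 0.755 after the same fit, so it decides nothing; with the feeder marker levels left in it gave -0.294, on the side of the labels, but ki/+ replicate 1 and ki/ki replicate 2 are the arrays with the lowest and the highest feeder markers, which sets them apart from each other.

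The feeder markers differed within genotypes, and 96.4% of the 28 were higher in the array labelled ki/ki replicate 2 than in ki/ki replicate 1. Replicate 2 was also higher for 100% of them in ki/+ and 92.9% in wild type. The median differences were 1.55 in ki/ki, 0.93 in ki/+ and 0.18 in wild type. Different shares of feeder cells in the samples could explain this, and how much of these transcripts the ES cells make themselves was not measured. The most abundant marker, Lgals1, ran from 12.29 in ki/+ replicate 1 to 13.54 in wild type replicate 2. A mesenchymal transition of the ES cells of ki/ki replicate 2 would lower the epithelial genes there and cannot be told apart from this. Their median was 0.43 above ki/ki replicate 1 (95% bootstrap interval 0.16 to 0.65), but that array had the lowest values of all 6. Against wild type their median was -0.19 (95% bootstrap interval -0.30 to -0.0851), which a larger share of feeder cells would give as well. Both intervals are for medians over genes in a single ki/ki replicate 2 array and do not measure the spread between cultures. With the feeder covariate 5 of 10 and 6 of 12 list calls against wild type were kept, and the loss of the feeder list itself is given by construction. With an estimated correlation, a separate setting without the covariate, 0 of these calls were kept.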
